A study of Homo sapiens with 12 samples.

How the data were processed

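The deposited count table held whole-number counts per gene for 12 libraries, per the file headers, and these were used without rounding. The deposited TPM table held TPM (transcript amounts scaled to gene length and library size) per gene, per the file headers, and the deposited comparison table repeated the same TPM values. That table also held log2 fold changes (log2) computed by the authors, and a p-value and an adjusted p-value for each transfection against the empty vector, per the file headers. It carries the name of DESeq2. The submitters' processing notes name STAR 2.5.3a, RSEM 1.2.31 and the hg19 genome, without saying which step made which table. All 3 tables listed the same 13001 genes. Library totals are counts over these genes. None of them carries the symbol SRRM4, so SRRM4's own transcript was not analysed here.

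Counts were normalized with TMM factors and filtered with filterByExpr, which removed no gene (smallest total 168, median 4536 counts per gene over 12 libraries). The 5 comparisons were tested in edgeR 4.0.16 (R 4.3.3) with robust quasi-likelihood F tests in 1 model of the 4 groups, without a block for replicate number. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes of a comparison. SE are those of the log2 fold changes, and CPM values are means ± SD over the 3 libraries of a group. The biological coefficient of variation was 2.98%. Counts of replicate pairs varied more than Poisson sampling (chi-square per degree of freedom 1.44 to 2.88 in 12 pairs, genes with at least 50 counts in the pair, largest p = 1.05e-214).

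The 32 gene lists, the 5 comparisons, the tests and most of the alternatives were fixed before the data were examined. Of the lists 30 were tested as sets in limma 3.58.1 with camera on log2 CPM (prior count 2) at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and 2 had fewer than 3 measured genes. KDM1A was left out of its list in the set tests. Each set was tested again with an estimated correlation and with fry. As used here, fry asks whether a list moved in a common direction, not whether it differed from other genes. Named genes were KDM1A and, among called genes with an average log2 CPM of at least 0 whose 3 libraries of a group all lay on the same side of the other group's, the 10 largest rises and 10 largest falls per comparison, plus, from each list described, up to 4 measured members with the smallest p, called or not. Genes known only by clone names were not named. Symbols were checked against lists of gene names and RefSeq genes (11196 current symbols, 903 older, 902 not matched). GC content and transcript length came from a GENCODE v29 annotation of GRCh38, matched by current or older symbol for 93.2% of genes. Gene positions were not used.

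The procedure was tested on simulated data in which 50 genes each were changed by 1.15, 1.25, 1.5 and 2-fold in libraries of the same depth and spread. Of these edgeR recovered 30, 60, 80 and 94% for SRRM4 against the empty vector, 26, 48, 94 and 96% for LSD1+8a, and 22, 68, 94 and 100% for LSD1. For LSD1+8a against LSD1 it recovered 48, 68, 90 and 96%, and for SRRM4 against LSD1+8a 28, 56, 90 and 96%. False calls made up 4.35, 3.65, 4.05, 9.58 and 7.53% of calls in these 5 simulations, so the last 2 exceeded the nominal 5%. Simulated sets with an effect were recovered in the right direction with an estimated correlation (largest adjusted p = 3.46e-06), and unchanged sets were not called. The simulated genes varied independently, and all members of a changed set shifted by the same 1.25-fold. Real lists had estimated correlations of up to 0.568 (cytosolic ribosomal proteins). The simulation therefore cannot show how often the set tests make false calls for correlated lists.

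Alternatives were relative log expression (RLE) size factors, the kind DESeq2 uses but computed in edgeR, upper-quartile factors, and removal of KDM1A before normalization. No filter, a stricter filter (at least 1 CPM in 6 libraries and an average log2 CPM of at least 1), the DESeq2 1.42.0 Wald test and limma-voom were also used. Further ones were limma-trend on log2 TPM with pseudocounts of 1 and 0.1, a block for replicate number, a fit of only the 2 groups compared, a threshold test against a 1.5-fold change (glmTreat), and leaving out each library in turn. For shared genes an unadjusted p under 0.05 in 1 of the 2 comparisons was also used. Thinning to equal totals of 10876293 counts, removal of GC and length trends, and removal of mitochondrial genes before normalization were added after the data were seen. Shared genes were compared with 50 simulations in which all libraries, the 3 shared controls included, were drawn without any group difference. All splits of 6 libraries into 3 and 3 were tested for each comparison.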

Results

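RNA-seq was carried out on LNCaP cells of clone FGC, an androgen-sensitive human prostate cancer line, after transient transfection. The 12 libraries fell into 4 groups of 3, which received an empty vector, LSD1, LSD1+8a or SRRM4. LSD1 is the histone lysine demethylase encoded by KDM1A, and LSD1+8a is its splice isoform that includes microexon 8a. SRRM4 is a neural splicing factor that promotes the inclusion of microexons. Per the series title, the question was whether SRRM4 mediates the splicing of LSD1+8a in neuroendocrine prostate cancer, and the comparisons below set each transfection against the empty vector, LSD1+8a against LSD1, and SRRM4 against LSD1+8a. The deposited table listed 13001 genes by symbol. Total counts were 12.75 to 13.57 M per empty-vector library, 11.66 to 12.57 M for LSD1, 12.11 to 13.36 M for LSD1+8a and 10.88 to 11.49 M for SRRM4. The labels do not say whether the 3 libraries of a group came from separate cultures, so every p-value measures only the spread between these libraries, which may be technical.

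KDM1A, the gene supplied by the LSD1 plasmids, followed the labels in every library. It stood at 94.3 ± 0.828 CPM (counts scaled to library size, mean ± SD, n = 3) with the empty vector and at 96.3 ± 4.06 CPM with SRRM4. In LSD1 libraries it reached 540 ± 40.5 CPM, a log2 fold change of 2.52 over the empty vector (adjusted p = 8.55e-05). In LSD1+8a libraries it reached 2268 ± 316 CPM, a log2 fold change of 4.59 (adjusted p = 9.1e-08). The LSD1+8a cells therefore carried 4.20-fold more KDM1A transcript than the LSD1 cells (log2 fold change 2.07, adjusted p = 1.54e-05), so that isoform and amount differed together. Gene counts do not separate plasmid from endogenous reads, or transcripts with microexon 8a from those without it. No listed gene carries the symbol SRRM4, so its transcript was not analysed here. No value therefore checks the labels of the SRRM4 libraries in the same way.

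**Figure D1:**
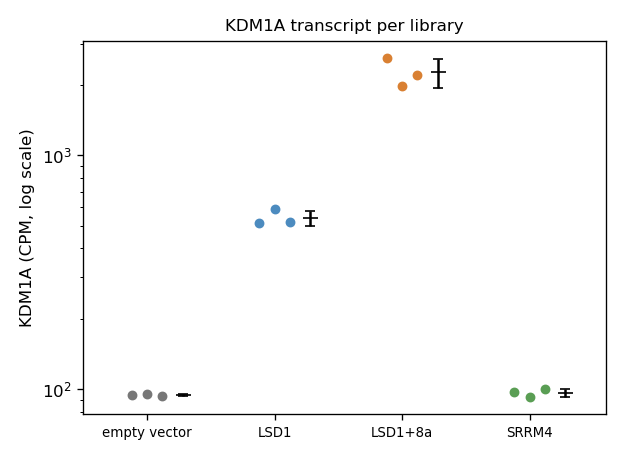
KDM1A in CPM (log axis) for each of the 12 libraries, by transfection; points are libraries, and the black mark and bar are the mean and SD of 3. Empty-vector and SRRM4 libraries lie between 92.0 and 100.1 CPM, LSD1 libraries between 514.6 and 586.6 CPM, and LSD1+8a libraries between 1983 and 2608 CPM.

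With SRRM4, LNCaP cells gained neuronal transcripts, interferon-stimulated transcripts and p53 target transcripts, and lost a little of their androgen receptor program. Synaptophysin (SYP), a synaptic vesicle protein used as a neuroendocrine marker, rose from 2.52 ± 0.608 to 27.1 ± 1.18 CPM (log2 fold change 3.42, SE 0.13, adjusted p = 2.01e-20). VGF, a neuropeptide precursor, rose from 1.91 ± 0.351 to 19.3 ± 1.32 CPM (log2 fold change 3.33), and the neuronal stathmin STMN3 rose from 9.07 ± 0.446 to 52.5 ± 0.996 CPM (log2 fold change 2.53). RSAD2, the antiviral protein viperin, rose by 2.95 on the log2 scale, and CDKN1A, the cell-cycle inhibitor p21, rose from 302 ± 11.1 to 603 ± 18.2 CPM (adjusted p = 4.89e-23). Across all 13001 genes, 581 were higher and 418 lower in SRRM4 than in the empty vector. Most changes were small: the median called rise was 0.27 and the median called fall -0.19 on the log2 scale, and 44 rises but none of the falls exceeded 2-fold.

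Many of the neuronal genes that rose are normally silenced outside neurons by the repressor REST. Of 47 listed REST targets 18 were measured. Among these 18, 11 were higher, none was lower and 7 were not called (12 higher and 1 lower when adjusted over the list alone). The list median was 0.45 (adjusted p = 1.04e-13). Examples were the atypical cadherin CELSR3 (2.05, from 14.7 ± 0.806 to 60.9 ± 3.07 CPM), the presynaptic scaffold BSN (1.21) and the JNK scaffold MAPK8IP2 (1.06). Only 8 of 36 listed neuroendocrine markers were measured, so that list was seen in part. Of the 8 measured, 4 were higher and 4 were not called, with the same counts over the list alone (median 0.25, adjusted p = 3.77e-05). Besides SYP and VGF the higher ones were SYT4, a synaptotagmin (0.52, adjusted p = 2.66e-08), and ONECUT2, a transcription factor of neuroendocrine tumours (0.49, adjusted p = 0.00207). The REST and neuroendocrine lists share 2 of their measured members. For the absence of lower REST targets in edgeR, 1 member was lower at an unadjusted p under 0.05, and neither DESeq2 nor limma-voom called any lower. Genes known to hold SRRM4-regulated microexons showed no common direction in their total expression. Of 51 measured, 6 were higher and 3 lower (8 and 4 over the list alone, median 0.02, adjusted p = 0.366), among them the phosphatase SYNJ1 (0.47), RAPGEF6 (0.36) and the liprin PPFIA2 (-0.27).

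Interferon-stimulated genes formed the largest single group of rises. Of 46 measured, 30 were higher, none was lower and 16 were not called (33 higher over the list alone, median 0.38, adjusted p = 1.03e-36). None of the 46 was lower at an unadjusted p under 0.05, nor was any called lower by DESeq2 or limma-voom. ISG15, a ubiquitin-like modifier, rose from 49.4 ± 1.35 to 103 ± 0.982 CPM (1.06, adjusted p = 2.98e-19). IFIT3 (2.22), OAS2 (2.13), IFIT2 (1.96) and OASL (1.72) were also among the largest rises, as was IFI44L (from 0.942 ± 0.371 to 3.81 ± 0.163 CPM). In the NF-kB list 11 of 26 genes were measured. Among these 11, 6 were higher and 1 lower, with the same counts over the list alone (median 0.16, adjusted p = 0.000701). The inhibitor of apoptosis BIRC3 (1.05), RELB (0.86) and NFKB2 (0.46) rose, whereas ZC3H12A, an RNase that limits inflammation, fell by 0.23.

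Among p53 targets 21 of 32 were higher, 1 was lower and 10 were not called (22 and 1 over the list alone, median 0.30, adjusted p = 7.07e-24). Besides CDKN1A, the oxidoreductase TP53I3 rose by 1.67 (from 6.35 ± 0.438 to 20.2 ± 1.43 CPM), ferredoxin reductase FDXR by 0.67 and the antiproliferative BTG2 by 0.56. The 1 lower member was SESN1 (-0.15), named after its value was seen. SERPINB5, the serpin maspin, rose from 8.29 ± 0.137 to 34.1 ± 0.0696 CPM (2.04). Mitotic genes were lower: of 40 in the G2/M list 9 fell (12 over the list alone) and 31 were not called, with a median of -0.09 (adjusted p = 7e-08). TOP2A, which untangles replicated DNA, fell by 0.26, the spindle factor TPX2 by 0.18 and the kinetochore protein CENPF by 0.17. None of the 40 was higher in edgeR, at an unadjusted p under 0.05, or in DESeq2 or limma-voom.

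Androgen receptor targets were slightly lower. Of 32 measured 7 were lower, 1 was higher and 24 were not called (10 and 2 over the list alone, median -0.09, adjusted p = 3.93e-06). Prostatic acid phosphatase ACPP fell by 0.45 (from 93.2 ± 1.93 to 68.1 ± 2.35 CPM), and KLK3, which encodes prostate-specific antigen, fell by 0.23 (from 3124 ± 56.6 to 2660 ± 39.4 CPM, adjusted p = 1.45e-06). The 1 higher member was ZNF385B (0.68), named after its value was seen. Luminal prostate markers had 5 of 15 lower and 1 higher (7 and 1 over the list alone, median -0.09, adjusted p = 0.000777, but 0.0613 with an estimated correlation). They share 4 measured members with the androgen receptor targets. Androgen-repressed genes had 4 of 20 lower and 2 higher (5 and 3 over the list alone, median -0.05, adjusted p = 0.0394, and 0.293 with an estimated correlation). That call ended without empty-vector replicate 1 (adjusted p = 0.0724) or 3 (0.129), or without SRRM4 replicate 2 (0.0932) or 3 (0.0509).

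Stress and metabolic genes moved in part. HMOX1, heme oxygenase, rose by 1.30, the small heat-shock protein HSPB8 by 1.37 and the autophagy receptor SQSTM1 by 0.31, within a heat-shock list of 20 that had 4 higher and 1 lower (5 and 1 over the list alone, median 0.04, adjusted p = 0.000797, and 0.308 with an estimated correlation). In the unfolded protein response and ATF4 list 11 of 35 were lower and 3 higher (15 and 4 over the list alone, median -0.09, adjusted p = 1.52e-05, and 0.0613 with an estimated correlation). The pseudokinase TRIB3 (-0.41) and the glycoprotein hormone STC2 (-0.28) fell, while SESN2 rose (0.53). Cholesterol and fatty acid synthesis had 11 of 32 higher (12 higher and 1 lower over the list alone, median 0.12, adjusted p = 8.72e-08, and 0.233 with an estimated correlation), with INSIG1 at 0.44 and FASN at 0.27. Immediate early genes had 4 of 21 higher (4 higher and 1 lower over the list alone, median 0.13, adjusted p = 0.000581, and 0.184 with an estimated correlation), including JUNB at 0.41. The immediate early call ended without empty-vector replicate 3 (adjusted p = 0.0592). Nuclear genes of oxidative phosphorylation had 4 of 64 higher, with the same count over the list alone (median 0.05, adjusted p = 0.000132, and 0.321 with an estimated correlation), including UQCRFS1 at 0.18. S-phase genes had 3 of 39 lower, with the same count over the list alone (median -0.04, adjusted p = 0.0394, and 0.558 with an estimated correlation). The S-phase call ended without empty-vector replicate 1 (0.0526) or 3 (0.251), or SRRM4 replicate 1 (0.25) or 3 (0.102).

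Transcripts of the mitochondrial genome made up 7.29 ± 0.1% of counts with the empty vector, 6.56 ± 0.156% with LSD1, 6.82 ± 0.257% with LSD1+8a and 6.75 ± 0.13% with SRRM4. Of 15 measured, 8 were lower and 1 was higher with SRRM4 (11 and 1 over the list alone, median -0.15, adjusted p = 7e-08, and 0.184 with an estimated correlation). The complex I genes MT-ND6 (-0.27) and MT-ND1 (-0.23) fell, and the ribosomal RNA MT-RNR1 rose (0.22). With LSD1+8a 1 of 15 was lower and the set call did not hold either (adjusted p = 0.426 with an estimated correlation). The list mean of LSD1+8a replicate 1 (-0.018 relative to the empty-vector mean) lay next to the lowest empty-vector library (-0.0166). Reads of these genes may be shared with nuclear copies.

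The other lists were not called with SRRM4. Histones had 1 of 17 higher (median 0.13, adjusted p = 0.0846) and cytosolic ribosomal proteins 2 of 78 lower (0.221). Polycomb and chromatin regulators had 1 higher and 3 lower of 35 (0.404). The list of the LSD1-CoREST complex and its cofactors had 1 higher and 1 lower of 23 (0.578). These were the deacetylase complex subunit MTA2 (0.22) and SVIL (-0.29). The histone list was called higher without SRRM4 replicate 2 (adjusted p = 0.0199), and the ribosomal list lower without empty-vector replicate 1 (0.0236) or SRRM4 replicate 2 (0.00965). Hippo/YAP targets had 2 higher and 1 lower of 10 (0.722), serine/arginine splicing factors 1 higher and 2 lower of 30 (0.858) and other splicing regulators 2 higher and 1 lower of 36 (0.799). Hypoxia and glycolysis had 2 of 31 lower (0.799) and nuclear-retained noncoding RNAs 1 of 7 higher (0.799). Genes of epithelial-mesenchymal transition went both ways among 7 measured, with fibronectin FN1 at 0.33 and vimentin VIM at -0.48. Their median was -0.03 (0.10 with limma-trend on TPM), their mean 0.04, and the test pointed up (0.799). No member of the nonsense-mediated decay list of 21 was called by edgeR, DESeq2 or limma-voom, against 3 higher and 3 lower at an unadjusted p under 0.05 (0.947). Basal epithelial markers had 1 of 5 lower (0.949), namely ITGA6 at -0.23. Their median (0.08) and mean (0.05) were above 0 while the test pointed down. None of 3 measured fibroblast markers was called by any of the 3 tools, with 1 higher at an unadjusted p under 0.05 (0.222). The median was also opposite in sign to the mean for other splicing regulators (-0.0039 and 0.01) and for serine/arginine factors (0.01 and -0.0039). Leukocyte and endothelial markers (VWF at -0.29, the other not called) and embryonic kidney markers (none called by any of the 3 tools, none under an unadjusted p of 0.05) had 2 measured genes each and were not tested as sets.

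With SRRM4, 16 of the 30 lists tested as sets were called, 9 higher and 7 lower. The calls of 7 held when the correlation between genes was estimated from these libraries: REST targets (adjusted p = 0.000892), interferon-stimulated genes (0.00067), p53 targets (0.00124), neuroendocrine markers (0.0142), NF-kB (0.0309), G2/M (0.0334) and androgen receptor targets (0.0334). The 10 largest named falls were smaller than the 10 largest rises. All 10 of the largest named rises kept their calls in every alternative, and FAM129A (-0.63, adjusted p = 1.45e-06) and VIM in every alternative except the 1.5-fold threshold. MAPK10 (-0.75), SLC22A10 (-0.69), PART1 (-0.61), THSD4 (-0.60), PCDHGA6 (-0.57), KHDRBS3 (-0.57), EIF4BP6 (-0.55) and PCDHGA7 (-0.48) each lost the call in at least 1 alternative or without 1 library. PCDHGA6 and PCDHGA7 share exons, and EIF4BP6 may share reads with its parent gene. The balance of rises and falls differed between settings: upper-quartile factors gave 497 higher and 561 lower. limma-trend on deposited TPM with a pseudocount of 1, which changes unit and test together, gave 254 and 73. DESeq2 called 328 higher and 235 lower. The number of lower genes was 262 without SRRM4 replicate 1, 268 without SRRM4 replicate 2 and 277 without SRRM4 replicate 3.

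**Figure D2:**
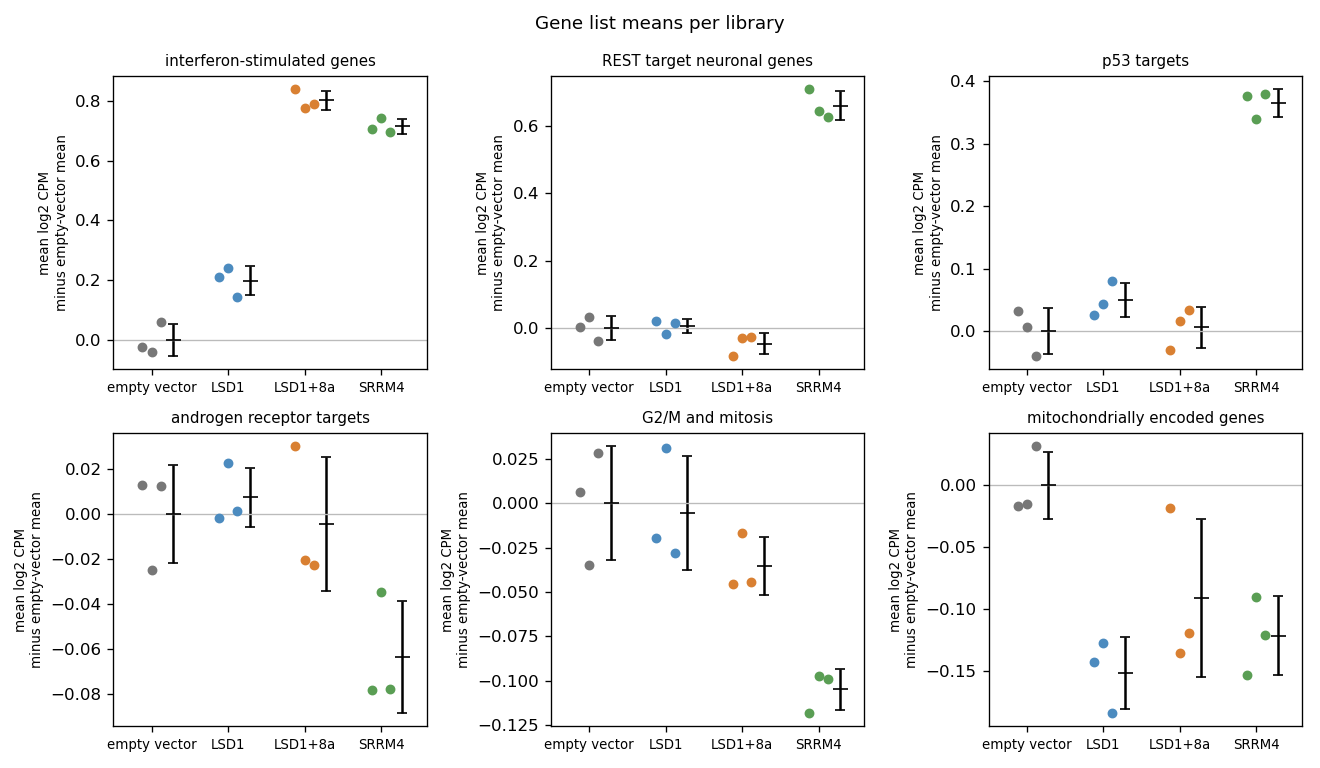
Mean log2 CPM of 6 gene lists per library, minus the mean of the 3 empty-vector libraries; points are libraries and the black mark and bar are the mean and SD of 3, and the vertical scale differs between panels. SRRM4 libraries stand at 0.66 ± 0.04 for REST targets and 0.36 ± 0.02 for p53 targets, while interferon-stimulated genes stand at 0.71 ± 0.02 with SRRM4, 0.80 ± 0.03 with LSD1+8a and 0.20 ± 0.05 with LSD1.

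LSD1+8a raised interferon-stimulated genes and little else. ISG15 rose from 49.4 ± 1.35 to 107 ± 4.1 CPM (log2 fold change 1.11, SE 0.04, adjusted p = 1.53e-19), IFI44L from 0.942 ± 0.371 to 6.58 ± 0.353 CPM (2.79) and OAS2, an activator of RNase L, from 1.86 ± 0.209 to 10.7 ± 0.666 CPM (2.51). IFI27 (2.24), IFITM1 (2.13), IFIT1 (2.06), IFIT3 (2.05), OASL (1.88), RSAD2 (1.67) and OAS1 (1.62) completed the 10 largest rises together with KDM1A. IFITM1 may share reads with its paralogs. In all, 37 genes were higher and 8 lower than with the empty vector, and 26 of the 37 belonged to the list of interferon-stimulated genes, of which 20 of 46 were not called (36 higher over the list alone, median 0.45, adjusted p = 9.67e-101). None of the 46 was lower at an unadjusted p under 0.05, nor called lower by DESeq2 or limma-voom.

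The neuronal and p53 genes that rose with SRRM4 were not called with LSD1+8a. edgeR, DESeq2 and limma-voom each called 0 of 18 REST targets (median -0.04, adjusted p = 0.0723), 0 of 8 neuroendocrine markers (median -0.07, adjusted p = 0.475), 0 of 32 p53 targets (median 0.0088, adjusted p = 0.879) and 0 of 32 androgen receptor targets (median 0.0066, mean -0.0049, adjusted p = 0.784). The REST set was called lower without empty-vector replicate 3 (adjusted p = 0.0372). At an unadjusted p under 0.05, 3 REST targets were lower, 1 androgen receptor target was higher, and no neuroendocrine marker or p53 target passed. CELSR3 was at -0.21 (adjusted p = 0.626) and MAPK8IP2 at -0.21 (adjusted p = 0.589). The androgen receptor median fell just below 0 (-0.0007) once GC and length trends were removed. Genes that fell included the histone demethylase KDM3A (-0.31), ZNF395 (-0.34), MAP1B (-0.15), CD2AP (-0.18) and MT-CO1 (-0.21). HNRNPUL2-BSCL2, a readthrough transcript that overlaps its neighbours, was also lower (-0.18). The largest called fall (-1.29), the only 1 beyond 2-fold, was in a gene outside the rule for named genes.

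Of 30 lists 8 were called and the interferon list alone held with an estimated correlation (adjusted p = 1.38e-05). The other calls rested on small medians: mitochondrial genes (1 of 15 lower, 9 over the list alone, median -0.09, adjusted p = 0.426 with an estimated correlation), hypoxia and glycolysis (1 of 31 lower, 3 over the list alone, median -0.05, 0.457), cytosolic ribosomal proteins (median -0.04, 0.481), the unfolded protein response (median -0.03, 0.457), G2/M (median -0.03, 0.481), nuclear oxidative phosphorylation (median -0.02, 0.554) and nuclear-retained noncoding RNAs (median 0.08, 0.481). In the last 5 of these edgeR, DESeq2 and limma-voom called no member, against 15, 3, 7 and 1 lower and 1 higher at an unadjusted p under 0.05. The unfolded protein response call ended without LSD1+8a replicate 3 (adjusted p = 0.0584). The G2/M call ended without empty-vector replicate 3 (0.23) or LSD1+8a replicate 1 (0.0531) or 3 (0.0699). The oxidative phosphorylation call ended without empty-vector replicate 3 (0.236) or LSD1+8a replicate 2 (0.0948) or 3 (0.16). The noncoding RNA call ended without empty-vector replicate 2 (0.105) or 3 (0.0596) or LSD1+8a replicate 2 (0.15) or 3 (0.196). Of the named rises 9 of 10 kept their calls throughout and RSAD2 lost its call with limma-trend on TPM, whereas none of the 6 named falls kept its call in every alternative. limma-trend on TPM gave 23 genes higher and 1 lower. The number of lower genes was 3 without empty-vector replicate 1, 5 without empty-vector replicate 2 and 24 without LSD1+8a replicate 1.

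Few genes were called with LSD1, the form without the microexon. Besides KDM1A, the interferon-stimulated genes ISG15 (from 49.4 ± 1.35 to 63.4 ± 1.54 CPM, log2 fold change 0.36, SE 0.05, adjusted p = 8.55e-05), IFI6 (0.64) and IFI27 (0.94) rose. The short noncoding RNA BCYRN1, which has many genomic copies (0.44), and 1 transcript known only by a clone name completed the 6 rises. All 7 falls were mitochondrial transcripts: MT-ND6 (-0.27), MT-ND5 (-0.25), MT-ND1 (-0.23), MT-CO1 (-0.21), MT-ND4 (-0.20), MT-ND2 (-0.19) and MT-CYB (-0.16). The mitochondrial list had 7 of 15 lower and 8 not called (12 lower over the list alone, median -0.17, adjusted p = 1.53e-27, and 0.0481 with an estimated correlation). The interferon list had 3 of 46 higher (9 over the list alone, median 0.09, adjusted p = 2.97e-13, and 0.0251 with an estimated correlation). OASL stood at 0.51 (adjusted p = 0.235). edgeR, DESeq2 and limma-voom called 0 of 18 REST targets, 0 of 8 neuroendocrine markers and 0 of 32 androgen receptor targets. At an unadjusted p under 0.05, 1 REST target was higher and 1 lower, 3 androgen receptor targets were higher and 1 lower, and no neuroendocrine marker passed.

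Hypoxia and p53 genes were called as sets with LSD1 at medians of 0.05 and 0.04, and these calls did not hold with an estimated correlation (adjusted p = 0.589 for both). No member of either was called by edgeR, DESeq2 or limma-voom, against 4 and 1 higher at an unadjusted p under 0.05. The hypoxia call ended without empty-vector replicate 3 (adjusted p = 0.0956), and the p53 call without empty-vector replicate 3 (0.22) or LSD1 replicate 3 (0.434). Of the 5 named rises KDM1A kept its call in every alternative, and ISG15 in every one except the 1.5-fold threshold, as did MT-ND1 among the 7 named falls. IFI27 (adjusted p = 0.051) and BCYRN1 (0.0512) lost the call without LSD1 replicate 3, and IFI6 (0.0567) without empty-vector replicate 2. The number of lower genes was 4 without empty-vector replicate 2, 3 without empty-vector replicate 3 and 1 without LSD1 replicate 3, and limma-trend on TPM gave 5 higher and 1 lower.

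The direct comparison of the isoforms set LSD1+8a against LSD1. Interferon-stimulated genes were higher with the microexon form: 22 of 46 were higher and 24 not called (36 over the list alone, median 0.40, adjusted p = 4.47e-79, and 3.58e-05 with an estimated correlation). No member was lower at an unadjusted p under 0.05, or called lower by edgeR, DESeq2 or limma-voom. IFI44L rose from 1.52 ± 0.816 to 6.58 ± 0.353 CPM (log2 fold change 2.10, SE 0.24), IFIT3 from 3.65 ± 0.166 to 12.9 ± 0.56 CPM (1.82) and ISG15 from 63.4 ± 1.54 to 107 ± 4.1 CPM (0.75, adjusted p = 1.62e-14). OAS2 (1.66), IFITM1 (1.54), IFIT1 (1.49), OASL (1.36), RSAD2 (1.35), BST2 (1.33) and IFI27 (1.30) were the other large rises. Because KDM1A was 4.20-fold higher in the same cells, an effect of the microexon and an effect of the transcript amount cannot be told apart here.

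Hypoxia and glycolysis genes were lower with LSD1+8a than with LSD1. Of 31 measured 5 were lower and 26 not called (9 over the list alone, median -0.13, adjusted p = 7.89e-23, and 0.106 with an estimated correlation). The phosphofructokinase regulator PFKFB4 (-0.42), KDM3A (-0.36), the oxygen sensor EGLN1 (-0.29) and the glucose transporter SLC2A1 (-0.24) fell. Other named falls were PPFIA4 (-0.76), C4orf48 (-0.44), PRR7 (-0.34), ZNF395 (-0.31), PPP1R3B (-0.30), RIMKLA (-0.28) and GCSH (-0.26). The largest called fall (-1.21), the only 1 beyond 2-fold, was in a gene outside the rule for named genes. In all 27 genes were higher and 15 lower. Of 30 lists 9 were called, and the interferon list alone held with an estimated correlation. Besides hypoxia these were mitochondrial genes (median 0.08, 1 higher over the list alone, adjusted p = 0.571 with an estimated correlation), cytosolic ribosomal proteins (median -0.03, 0.756), nuclear oxidative phosphorylation (median -0.02, 0.756), the unfolded protein response (median -0.04, 0.527), cholesterol synthesis (median -0.03, 0.756), p53 targets (median -0.02, 0.62) and serine/arginine factors (1 of 30 higher, 2 over the list alone, median 0.02, 0.62). In the first 6 of these 7 lists edgeR, DESeq2 and limma-voom called no member. At an unadjusted p under 0.05 they held 5 higher mitochondrial genes, and 2, 4, 4, 1 and 4 lower genes in the order given.

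Several of these small list calls in the isoform comparison ended when 1 library was left out. All of these except the mitochondrial call ended for more than 1 choice of library. Without LSD1 replicate 1 the ribosomal call ended at an adjusted p of 0.362, the oxidative phosphorylation call at 0.542, the cholesterol call at 0.185 and the serine/arginine call at 0.098. Without LSD1 replicate 2 the p53 call ended at 0.0649. Without LSD1 replicate 3 the serine/arginine call ended at 0.202, the p53 call at 0.371 and the unfolded protein call at 0.113. Without LSD1+8a replicate 1 the p53 call ended at 0.479, the mitochondrial call at 0.0605 and the ribosomal call at 0.516. Without LSD1+8a replicate 2 the serine/arginine call ended at 0.0952, the p53 call at 0.0579, the unfolded protein call at 0.0687 and the cholesterol call at 0.563. Without LSD1+8a replicate 3 the serine/arginine and oxidative phosphorylation calls ended at 0.0527, the unfolded protein call at 0.0564 and the cholesterol call at 0.813. Of the named genes 8 of 10 rises kept their calls in every alternative, and IFI44L and RSAD2 lost theirs with limma-trend on TPM. None of the 10 falls kept its call in every alternative, even with the 1.5-fold threshold left aside. The number of lower genes was 6 without LSD1 replicate 1, 9 without LSD1 replicate 2 and 8 without LSD1 replicate 3. DESeq2 called 7 lower, and limma-trend on TPM gave 19 higher and 2 lower.

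SRRM4 and LSD1+8a were also compared directly, as a test of the difference between the splicing factor and the isoform named in the series title. Neuronal and p53 genes were higher with SRRM4. VGF rose from 1.65 ± 0.164 to 19.3 ± 1.32 CPM (log2 fold change 3.54, SE 0.16, adjusted p = 1.53e-18), SYP from 2.69 ± 0.412 to 27.1 ± 1.18 CPM (3.33), STMN3 by 2.74 and CELSR3 by 2.26. SERPINB5 (1.98), PSD (1.84), DISP2 (1.59), TP53I3 (1.55), AP3B2 (1.43) and HMOX1 (1.41) followed. REST targets had 12 of 18 higher (13 higher and 1 lower over the list alone, median 0.52, adjusted p = 2.34e-15), neuroendocrine markers 4 of 8 higher (4 and 1 over the list alone, median 0.26, adjusted p = 3.11e-06), and p53 targets 20 of 32 higher and 1 lower (24 and 1 over the list alone, median 0.26, adjusted p = 6.2e-24), with CDKN1A at 0.98 and FDXR at 0.68. Androgen receptor targets had 8 of 32 lower and 2 higher (15 and 3 over the list alone, median -0.08, adjusted p = 1.51e-06), with ACPP at -0.46, TMPRSS2, a luminal protease, at -0.19 and KLK3 at -0.19. These 4 calls held with an estimated correlation (adjusted p = 0.00112, 0.00866, 0.00177 and 0.0399).

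Interferon-stimulated genes were similar in SRRM4 and LSD1+8a but not identical. Of 46, 4 were higher and 8 lower with SRRM4 (5 and 14 over the list alone, median -0.08, adjusted p = 0.0231, and 0.293 with an estimated correlation). RSAD2 was higher (1.28), as was the peptide transporter TAP1 (0.29), while IFI44L (-0.79), BST2 (-0.78), IFI27 (-0.76) and DDX58, the RNA sensor RIG-I (-0.44), were lower. The set call ended without LSD1+8a replicate 1 (adjusted p = 0.116) or SRRM4 replicate 3 (0.0572). The remaining named falls were KDM1A (-4.56), CLU (-0.85), NEK3 (-0.72), PART1 (-0.72), and POTEJ (-0.87), SERHL2 (-0.74) and RPS9P1 (-0.71), which may share reads with related sequences. In all 574 genes were higher and 412 lower, whereas upper-quartile factors gave 492 and 497, without an excess of rises. Of the named genes 9 of the 10 named rises kept their calls in every alternative, the exception being AP3B2 with limma-trend on TPM. Of the 10 named falls KDM1A kept its call in every alternative, and BST2 and IFI27 in every one except the 1.5-fold threshold.

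The other lists called between SRRM4 and LSD1+8a did not hold with an estimated correlation. They were NF-kB (5 of 11 higher and 1 lower, 6 and 1 over the list alone, adjusted p = 0.0582 with an estimated correlation), cholesterol synthesis (10 of 32 higher, 13 over the list alone, 0.214), nuclear oxidative phosphorylation (5 of 64 higher, 13 over the list alone, 0.2), immediate early genes (6 of 21 higher, 7 higher and 1 lower over the list alone, 0.191) and heat shock (5 of 20 higher, 7 over the list alone, 0.293). Hypoxia had 3 of 31 higher (6 over the list alone, 0.505) and ribosomal proteins 1 of 78 higher (none over the list alone, 0.75). G2/M had 2 of 40 lower (10 over the list alone, 0.191), the unfolded protein response 7 of 35 lower and 2 higher (9 and 5 over the list alone, 0.305), luminal markers 3 of 15 lower and 1 higher (4 and 1 over the list alone, 0.2) and S phase 3 of 39 lower, with the same count over the list alone (0.563). Without LSD1+8a replicate 1 the unfolded protein call ended at an adjusted p of 0.258, the S-phase call at 0.497 and the ribosomal call at 0.857. Without SRRM4 replicate 1 the unfolded protein call ended at 0.111 and the S-phase call at 0.262. Without SRRM4 replicate 2 the ribosomal call ended at 0.207, and without SRRM4 replicate 3 the luminal call ended at 0.0648 and the S-phase call at 0.0985. DESeq2 called 319 genes higher and 203 lower, and limma-trend on TPM 134 and 77. Genes higher numbered 371 without LSD1+8a replicate 2, 379 without LSD1+8a replicate 3 and 341 without SRRM4 replicate 2. Genes lower numbered 241 and 230 without those LSD1+8a libraries, 251 without SRRM4 replicate 1 and 220 without SRRM4 replicate 2.

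**Figure D3:**
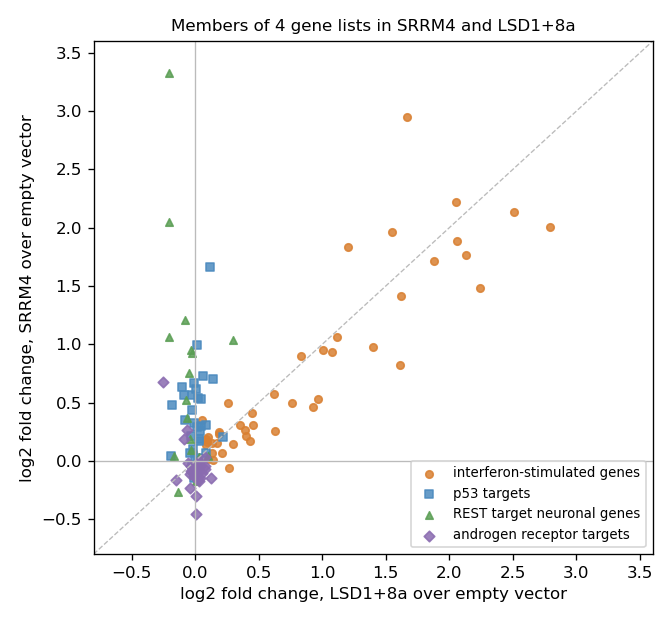
Log2 fold change over the empty vector with LSD1+8a (horizontal) and with SRRM4 (vertical) for each measured member of 4 gene lists; the dashed line marks equal change. Interferon-stimulated genes spread along the dashed line (medians 0.45 with LSD1+8a and 0.38 with SRRM4), while REST targets (-0.04 and 0.45) and p53 targets (0.0088 and 0.30) moved along the vertical axis.

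SRRM4 and LSD1+8a shared 35 called genes in the same direction, 31 higher and 4 lower, among 13000 genes without KDM1A, and 25 of the 35 were interferon-stimulated genes. The others included the interferon-related helicase HELZ2, LGALS3BP and TRANK1, all higher and named after their values were seen, and KDM3A, ZNF395, CD2AP and MT-CO1, lower. MAP1B went in opposite directions. The LSD1+8a calls of CD2AP and MAP1B were fragile: they were lost in 11 and 8 of the alternatives and left-out libraries, the 1.5-fold threshold not counted, and both were lost in the fit of only the 2 groups. Independent lists of those sizes would share 1.61 higher and 0.257 lower genes. Simulated groups with no effect, set against the same 3 simulated controls, shared 0.12 and 0.04 on average. SRRM4 and LSD1 shared 5 higher and 6 lower genes (independent lists 0.224 and 0.225, simulated 0.12 and 0), of which the 6 falls were mitochondrial. LSD1+8a and LSD1 shared 4 higher genes and 1 lower (0.0139 and 0.00431, simulated 0.14 and 0.02), among them IFI6, IFI27, ISG15 and MT-CO1. The 3 empty-vector libraries cannot be divided between comparisons, so part of each excess may come from the shared controls. No gene differed between the simulated groups, so the simulated numbers of shared genes cannot show how large that part is. Across genes, which are not independent replicates, the fold changes correlated at r = 0.37 for SRRM4 and LSD1+8a (0.49 simulated), 0.41 for SRRM4 and LSD1 (0.47 simulated) and 0.52 for LSD1+8a and LSD1 (0.49 simulated). Their covariance exceeded the simulated value by 0.00303 in the first pair and 0.00181 in the next, and was -0.000317 relative to it in the last.

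The deposited comparison table of the authors was compared gene by gene with these results. It listed 563 genes under an adjusted p of 0.05 for SRRM4 (328 higher and 235 lower), of which 548 were also called here. For LSD1+8a it listed 44 (35 higher and 9 lower), with 37 called in both. For LSD1 it listed 19 (1 higher and 18 lower), with 8 called in both, and it gave an adjusted p for 651 genes only. The authors' p-values adjusted over all genes gave 16 for LSD1, as many as DESeq2 gave here (6 higher and 10 lower). Fold changes in the table and in the fits described here correlated across genes at r of at least 0.999 in each comparison.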

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

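The tests of LSD1 transcript amount and of plasmid or transfection differences in this part were chosen after the result was seen, and those of depth and of GC and length were added after the data were seen, though before their own outcomes were known.

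Interferon-stimulated genes rose with SRRM4 as well as with LSD1+8a. The amount of LSD1 transcript is not a candidate explanation for SRRM4, where KDM1A stood at 0.03 while the list median was 0.38 (adjusted p = 0.00067 with an estimated correlation). A difference in library depth left 29 of 30 calls in place after thinning. A plasmid preparation or transfection that differed between the groups remains possible, because the lowest SRRM4 library lay 0.63 above the highest empty-vector library on the log2 scale, and any effect common to a whole group would give such a gap.

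The same list was higher with LSD1+8a than with LSD1 by a median of 0.40 (adjusted p = 3.58e-05 with an estimated correlation). Here the amount of LSD1 transcript could explain the difference, since the lowest KDM1A level in LSD1+8a was 3.38 times the highest in LSD1 and no libraries of equal amount exist. Library depth left 22 of 22 calls in place after thinning. A plasmid or transfection difference also stays open, with a gap of 0.53 between the groups. Hypoxia and glycolysis genes were lower in the same comparison by a median of -0.13, with 29 of 31 below 0. The set call did not hold with the estimated correlation between these genes of 0.312 (adjusted p = 0.106).

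Many genes were called with SRRM4, most by small folds. Library depth might have mattered because the SRRM4 libraries were the shallowest, yet 851 of 999 calls were kept after thinning and 934 genes were called in all. After removal of GC and length trends 947 of 999 were kept, with values for 98% of the called genes.

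Splitting the 6 libraries of a comparison into 3 and 3 in other ways leaves 10 splits, too few for a share under 0.05. The real split called 999 genes for SRRM4 against the empty vector (highest other 0), 45 for LSD1+8a (15), 13 for LSD1 (1), 42 for LSD1+8a against LSD1 (3) and 986 for SRRM4 against LSD1+8a (2). In each of the 5 comparisons 1 split, the real one, called that many.

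The listed genes did not cover all transcripts. In SRRM4 libraries 1.42% of TPM lay outside them, against at most 0.896% in the empty-vector libraries, and which transcripts these were was not analysed here.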

How the results depend on the processing

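Thinning, removal of GC and length trends, and removal of mitochondrial genes were chosen after the data were seen; the other alternatives were fixed earlier. The cause of a changed count was not tested unless the setting itself brings it about, as the 1.5-fold threshold does.

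For SRRM4 against the empty vector (581 higher, 418 lower), DESeq2 gave 328 and 235, TPM + 1 gave 254 and 73, TPM + 0.1 gave 251 and 74, and the 1.5-fold threshold gave 40 and 0. Leaving out a library gave 393 to 476 higher and 262 to 334 lower. For LSD1+8a against the empty vector (37 and 8), TPM + 1 and TPM + 0.1 each gave 23 and 1, the threshold 15 and 0, and the fit of only these 2 groups 5 lower. Leaving out a library gave 3 to 24 lower. For LSD1 against the empty vector (6 and 7), both TPM scales gave 1 lower, the threshold 2 and 0, and the fit of only these 2 groups 12 lower. Leaving out a library gave 1 to 7 lower. For LSD1+8a against LSD1 (27 and 15), DESeq2 gave 7 lower, TPM + 1 gave 2 lower, TPM + 0.1 gave 17 and 2, and the threshold 13 and 0. Leaving out a library gave 6 to 16 lower. For SRRM4 against LSD1+8a (574 and 412), DESeq2 gave 319 and 203, TPM + 1 gave 134 and 77, TPM + 0.1 gave 127 and 76, and the threshold 23 and 1. Leaving out a library gave 341 to 590 higher and 220 to 416 lower. Shared same-direction genes with an unadjusted p in 1 comparison numbered 151, 136 and 33, against 35, 11 and 5.

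KDM1A in SRRM4 against the empty vector, which was not called, turned from 0.03 to -0.0053 with TPM + 1 and -0.0054 with TPM + 0.1. Of 246 named gene results, the call was lost in 53 with DESeq2, 15 with limma-voom, 115 with TPM + 1, 118 with TPM + 0.1, 188 with the threshold, 16 with a block, 11 with only 2 groups, 13 after thinning, 11 after removing GC and length trends and 4 with upper-quartile factors. It was lost in 284 of the leave-one-out results, against 1192 kept. No call was lost with RLE size factors, the stricter filter, or removal of KDM1A or mitochondrial genes. "No filter" removed no gene and is no separate setting.

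Of 53 called lists 15 held with an estimated correlation, and all held with the stricter filter and the block. fry, which tests a list for a common direction of change and not against the other genes, passed 29 of the 53. That is a different question from the one behind the calls. Leaving out libraries ended 52 of 318 list results. Leaving out a library also brought 32 calls of lists not called otherwise. Among them were ribosomal proteins in LSD1 against the empty vector without LSD1 replicate 1 (adjusted p = 3.18e-05), cholesterol synthesis in LSD1+8a against the empty vector without LSD1+8a replicate 1 (0.000122), and mitochondrial genes in SRRM4 against LSD1+8a without LSD1+8a replicate 2 (0.00653) or 3 (0.0346) or SRRM4 replicate 2 (0.0273). With fry the microexon genes passed in that comparison (0.0175). The replicate block gave 518 higher and 369 lower for SRRM4 against the empty vector. Residuals of libraries with the same number correlated at -0.16 to 0.14, those with different numbers at up to 0.12, and 6 of 12 libraries correlated best with their own number. Between the empty vector and LSD1+8a all 3 same-number pairs were positive (0.14, 0.0764 and 0.0999) and 5 of 6 different-number pairs negative. Residuals are deviations from the group mean and cancel within a group. Positive same-number pairs thus make the others negative on balance, and the negative pairs are no separate evidence. The replicate numbers thus did not pair the libraries of all groups, and whether they pair those 2 groups stays open. The block gave 36 higher and 7 lower there.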

Other observations

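For the p53 hypothesis the comparison with LSD1+8a was chosen after the result was seen, and the GC and length test was added after the data were seen, though before its own outcome was known.

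Some transcripts shared by SRRM4 and LSD1+8a were not members of the interferon list. LGALS3BP, a secreted glycoprotein, HELZ2, TRANK1, HSH2D and RARRES3 were higher in both, and were named after their values were seen. Whether these 5 belong to the same interferon response was not tested, so they are no evidence of a separate shared response. The histone demethylase KDM3A and ZNF395 were lower in both. Their LSD1+8a calls were lost in 4 and 2 of the alternatives and left-out libraries, the 1.5-fold threshold not counted.

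The rise of p53 targets with SRRM4 may be a response separate from the interferon-stimulated genes; this is a hypothesis only. The interferon list was higher by a similar amount with LSD1+8a, yet the p53 median there was 0.0088 against 0.30 with SRRM4. The p53 list also differed between SRRM4 and LSD1+8a (adjusted p = 0.00177 with an estimated correlation). A GC or length trend left 21 of 21 calls in place, with values for 100% of the list. An experiment that could test it would measure CDKN1A and ISG15 after SRRM4 with and without a block of interferon signalling, to see whether CDKN1A still rises where ISG15 does not.

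Whether microexon 8a itself raises interferon-stimulated genes could be tested with LSD1 and LSD1+8a plasmids titrated to equal KDM1A levels, which here differed by at least 3.38-fold. Separate preparations of both plasmids could address whether the gap of 0.53 between these groups came with a preparation.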
